A study of Canis lupus familiaris with 8 samples.

How the data were processed

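Uterine tissue from bitches in diestrus was measured on Affymetrix arrays after amplification and labelling with whole-transcript kits. Per the labels, 100 ng of total RNA from each of 8 pools was used, with 4 pools from clinically healthy uteri and 4 from uteri with pyometra. The design text gives 20 healthy dogs and 23 dogs with pyometra, 43 in all. The number of dogs in each pool and their identity are not given in the sources used here. The labels call the pools biological replicates, so that every p-value of a single gene measures the spread between pools and not between dogs. The camera p-values of gene lists, described below, set the members against all other genes at an assumed correlation. They do not measure the spread between dogs either. The shared replicate numbers were not taken as pairs.

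The deposited values were log2 signals per probe set, made by the authors with RMA (background correction, quantile normalization and median polish), which the submitters' processing notes name without a version. The software and the probe annotation behind them are not given in the sources used here. The deposited table held 32391 probe sets on all 8 arrays and no detection calls, so that absence of a transcript could not be called. Control probe sets could not be told from unnamed ones in the tables used here, and all probe sets therefore stayed in the test, a departure from the plan to leave controls out. The number of arrays limits the precision.

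Names came from the platform's annotation table. It gave 1 gene symbol to 16878 probe sets, several to 289 and none to 15224. The Entrez identifiers of 16663 of the 1-symbol probe sets were found in the RefSeq annotation of the dog assembly UU_Cfam_GSD_1.0 and those of 215 were not; 0 symbols changed. A gene was represented by its 1-symbol probe set with the highest mean over the 8 arrays, which left 16295 genes. Of 521 genes with several probe sets, 31 were called only through another probe set and 1 had calls in opposite directions. Probe sequences and positions were not used here, so that signal from close relatives of a gene is not excluded.

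Differences were tested with limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the log2 values, pyometra minus healthy, without a covariate. All p-values of single genes are adjusted by the Benjamini-Hochberg method over the 32391 probe sets, and a gene was called at an adjusted p under 0.05. Errors of differences are standard errors from the fit, and errors of levels are SD over the 4 pools of a group. Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, against all other genes, with Benjamini-Hochberg adjustment over 26 lists. The same lists were tested with camera with a correlation estimated from the data and on ranks. They were also tested with fry, which asks whether the genes of a list move on balance in a direction and does not compare them with other genes. Of 704 genes in the lists, 608 were measured, some through a synonym in the annotation (CASP1 through CASP4 and CD1A through CD1A6). A list needed at least 3 measured members. Called members were also counted with adjustment over the list alone.

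The test, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule took the 10 genes with the largest change in each direction among called genes whose groups did not overlap, up to 3 called members of each list with the largest change (or the member with the smallest p where none was called), and IL1B, IL6, CXCL8, TNF, PTGS2, PTGES, TLR2, TLR4, PGR and ESR1. Genes named outside it are said to have been chosen after their values were seen.

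Alternatives were quantile normalization, median centring of each array, a filter that removed probe sets under the 30th percentile of mean signal in both groups, the mean of all probe sets of a gene, variance moderation with a trend and robust settings, array weights, a block for the replicate number, an adjusted p under 0.01, and leaving out each pool in turn. A test of 1-symbol probe sets alone and counts of list members without each pool or after the filter on dim probe sets were added after the data were seen. The 8 pools were also split in all 35 ways into groups of 4. Pools were compared by Pearson correlation and principal components over all probe sets. The procedure was tested on simulated data of the same size, with 50 changed probe sets at each of 4 sizes. It recovered 40% of those changed by 1 on the log2 scale, 88% of those changed by 2, 92% of those changed by 3 and 100% of those changed by 4. Of 174 calls, 14 (8.05%) were false. The simulated noise was independent between probe sets, and far fewer probe sets were changed than were called in the real data. These rates therefore need not hold for the real data.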

Results

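Gene expression was measured in the middle part of the left uterine horn of mongrel bitches that underwent ovariohysterectomy in diestrus. Pyometra, in which the uterus fills with infected fluid, was recognised by that fluid and by bacterial culture of it. The healthy group comprised 4 pools of RNA from 20 dogs, and the pyometra group 4 pools from 23 dogs. Median log2 signals of the 8 arrays lay between 5.31 and 5.43, and signals ran from 2.07 to 13.52. Correlations between arrays were 0.951 to 0.980 within the healthy group, 0.927 to 0.979 within the pyometra group and 0.842 to 0.941 between the groups. Principal component 1 held 56.8% of the variance and separated the groups. Principal component 2 held 14.7% and set pyometra pool 1 (70.9) apart from the other pyometra pools (-47.5 to -25.0).

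**Figure D1:**
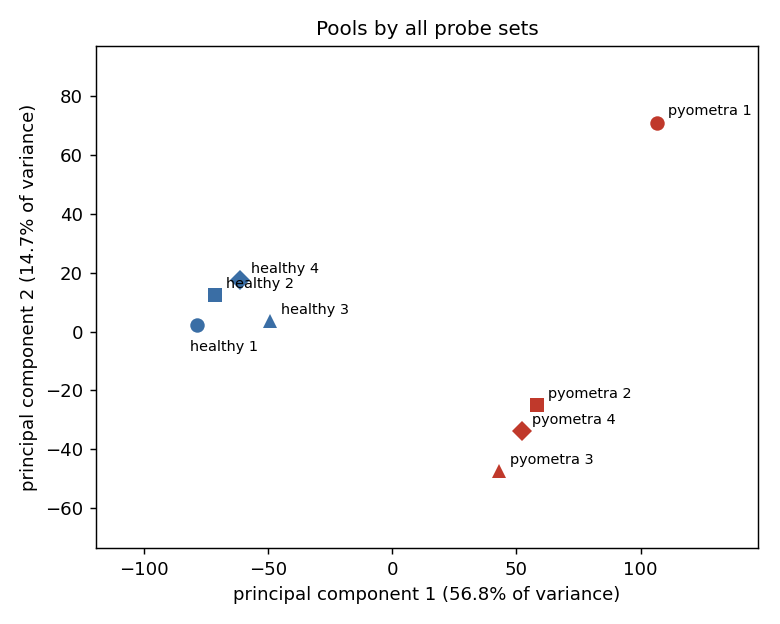
Each point is 1 pool of uterine RNA (healthy blue, pyometra red) placed by its scores on principal component 1 (horizontal, 56.8% of the variance) and principal component 2 (vertical, 14.7%), without units. The 4 pyometra pools lie at scores of 43.1 to 107 on component 1 and the 4 healthy pools at -78.5 to -49.2, with pyometra pool 1 alone at 70.9 on component 2.

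The series asks which genes of the inflammatory response change in the uterus with pyometra, and the comparison of diseased with healthy uteri in the same phase of the cycle addresses it. Pyometra uteri held much more transcript of secreted defence proteins, matrix proteases, chemokines and leukocyte markers than healthy uteri. On the log2 scale, with SD over 4 pools, SLPI, a secreted inhibitor of neutrophil elastase, rose from 5.24 ± 0.24 to 12.04 ± 0.22, the collagenase MMP13 from 4.07 ± 0.13 to 10.65 ± 0.86 and the neutrophil-attracting chemokine CXCL8 from 5.65 ± 0.91 to 11.57 ± 0.74. EPHA7, an ephrin receptor, fell from 10.34 ± 0.74 to 4.31 ± 0.36, and LGR5, a receptor that marks epithelial stem cells and strengthens Wnt signalling, from 8.46 ± 1.07 to 4.66 ± 0.36. Lists of genes for cytokines, leukocytes, antimicrobial proteins, matrix proteases, cell division and glycolysis rose, and the list of hormone receptors and progesterone response fell. These list calls were made with camera at a preset correlation, and 0 of the 26 lists passed with an estimated correlation (lowest adjusted p = 0.0971).

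Of 16295 genes, 1532 were higher and 1584 lower in pyometra (19.1% called), and 1024 and 814 of these differed at least 2-fold. The groups did not overlap in 4674 genes (28.7%), where chance gives 2.86%. The median difference was 1.31 among the higher genes, -1.02 among the lower genes and 0.02 over all genes. Counts moved by more than 1.5 times without healthy pool 1 (974 higher, 913 lower), healthy pool 2 (933 higher, 823 lower), pyometra pool 2 (984 lower) or pyometra pool 4 (1050 lower). Without pyometra pool 1, 1706 genes were higher and 1467 lower. Levels near 4 lie by the lower quartile of the arrays (3.97 to 4.13) and are not shown to be above background, so that differences measured against them are not exact folds.

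Among the genes with the largest rises, given as log2 differences with their SE, SLPI rose by 6.80 ± 0.16 (adjusted p = 1.29e-06), from a level of 5.24 ± 0.24 in healthy pools to 12.04 ± 0.22. DHRS9, a dehydrogenase of retinoid and steroid metabolism, rose by 6.64 ± 0.31 (adjusted p = 3.45e-05). MMP13 rose by 6.59 ± 0.38 (adjusted p = 7.01e-05), with healthy pool 3 at 4.26 and the other healthy pools at 3.99 to 4.02. CXCL8 rose by 5.92 ± 0.50 and SMPDL3A, a phosphodiesterase related to acid sphingomyelinase, by 5.70 ± 0.46. TFPI2, an inhibitor of serine proteases, rose by 5.52 ± 0.57. ATP12A, a proton and potassium pump, rose by 5.44 ± 0.74 (adjusted p = 0.0030), with healthy pool 3 at 6.67 and the other healthy pools at 3.87 to 4.21. S100A8, a subunit of calprotectin, rose by 5.20 ± 0.87 (adjusted p = 0.0071), the collagenase MMP1 by 5.20 ± 0.47 and the matrix glycoprotein THBS4 by 4.98 ± 0.47.

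The deepest fall was that of EPHA7, which fell by 6.03 ± 0.36 (adjusted p = 9.09e-05), from 10.34 ± 0.74 to 4.31 ± 0.36. NCKAP5 fell by 3.85 ± 0.22, while LGR5 changed by -3.80 ± 0.48 and HMGCLL1, an enzyme that splits hydroxymethylglutaryl-CoA, by -3.73 ± 0.32. The neural adhesion protein NEGR1 changed by -3.55 ± 0.28, the fibulin EFEMP1 by -3.38 ± 0.43, SLIT2, a secreted ligand of ROBO receptors, by -3.32 ± 0.46, and TMEM232 by -3.30 ± 0.32. MIR218-1, a microRNA gene within an intron of SLIT2, changed by -3.45 ± 0.66 (adjusted p = 0.0118), with healthy pool 4 at 9.55 and the other healthy pools at 6.39 to 6.62, and its probe set is not shown to read the microRNA apart from its host transcript. SULT1D1, a sulfotransferase, changed by -3.74 ± 0.84 (adjusted p = 0.0217). The call of SULT1D1 was lost without healthy pool 2 (-3.79), pyometra pool 2 (-3.74) or pyometra pool 4 (-3.75).

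**Figure D2:**
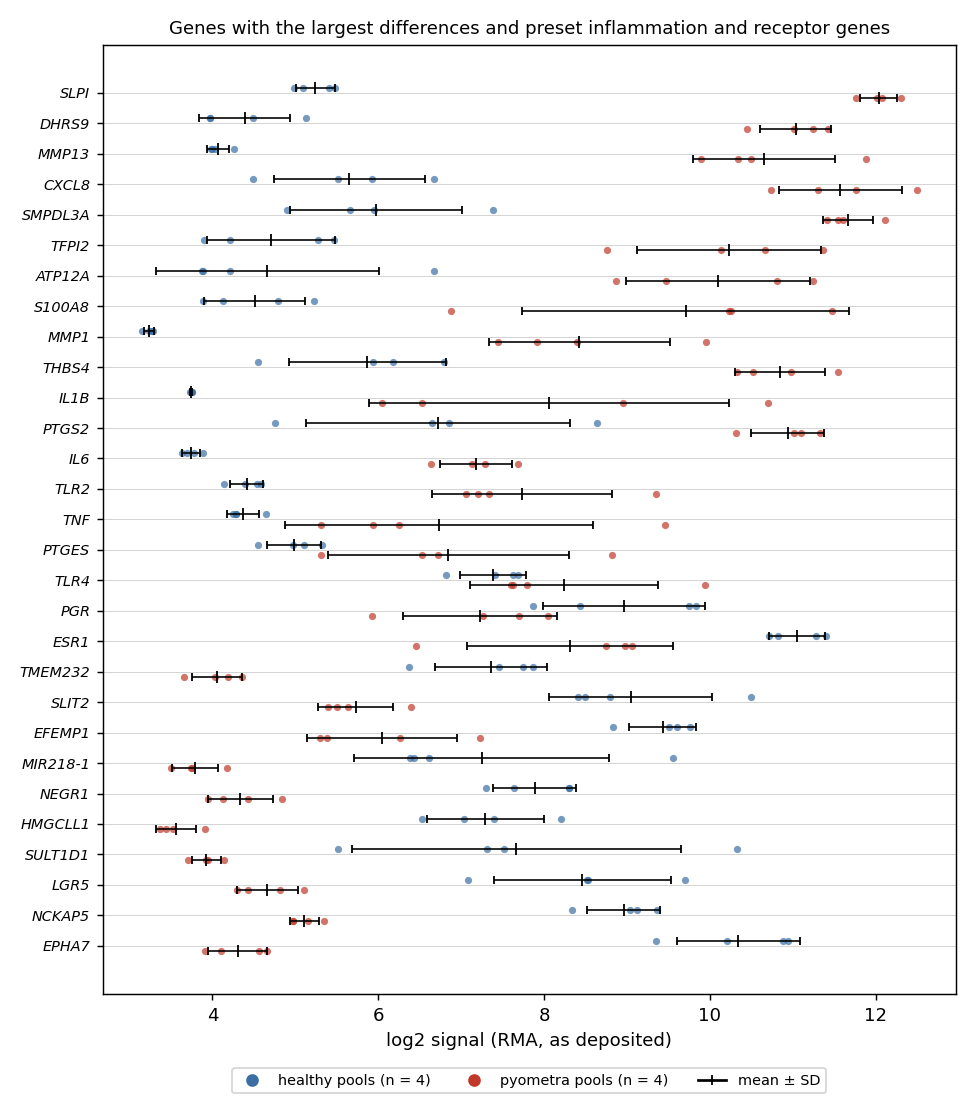
Log2 signal (horizontal axis, as deposited) of named genes (vertical axis) in each pool, where each point is 1 pool (healthy blue, pyometra red) and the tick and bar give the mean and SD of the 4 pools of a group. SLPI lies at 5.24 ± 0.24 in healthy and 12.04 ± 0.22 in pyometra pools, and EPHA7 at 10.34 ± 0.74 and 4.31 ± 0.36.

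Inflammatory cytokines and chemokines rose as a list, with 19 of 41 measured members higher and 1 lower (27 and 1 adjusted over the list alone). Their median difference was 1.59 (camera adjusted p = 5.81e-11; adjusted p = 0.0971 with an estimated correlation). Besides CXCL8, IL1B, a fever-inducing cytokine of macrophages, rose by 4.31 ± 0.92 (adjusted p = 0.0176) and IL6, which induces acute phase proteins, by 3.44 ± 0.21 (adjusted p = 9.63e-05). TNF differed by 2.37 ± 0.79 without passing the test (adjusted p = 0.0793), with healthy pool 3 at 4.65 and the other healthy pools at 4.25 to 4.28. Without pyometra pool 1 the difference of TNF was 1.46 (adjusted p = 0.0065). The lower member was CXCL12, a chemokine that holds leukocytes in tissues, which changed by -1.94 ± 0.38 and is named after its value was seen.

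Leukocyte markers rose in 4 lists. Neutrophil markers had 13 of 23 members higher and 0 lower (17 and 0 adjusted over the list alone) and a median difference of 2.86 (camera adjusted p = 2.30e-08; adjusted p = 0.246 with an estimated correlation). The calcium-binding proteins S100A8, S100A12 (4.96 ± 0.85) and S100A9 (4.89 ± 0.74), abundant in neutrophils, changed most. Monocyte and macrophage markers had 11 of 16 members higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 2.14 (camera adjusted p = 2.29e-09; adjusted p = 0.155 with an estimated correlation). FCGR1A, the high-affinity IgG receptor, rose by 3.57 ± 0.68 and the lipopolysaccharide co-receptor CD14 by 3.51 ± 0.43. TYROBP, a signalling adaptor of myeloid receptors, rose by 3.12 ± 0.41, with pyometra pool 1 at 11.10 and the other pyometra pools at 9.34 to 9.45. The mean of the neutrophil markers over the healthy mean was 4.36 in pyometra pool 1 and 1.28 to 2.37 in the other pyometra pools, and that of the macrophage markers 2.76 and 1.61 to 1.92. Without that pool, the neutrophil list had 16 members higher and a median of 2.03. Called neutrophil markers numbered 8 without healthy pool 1 and 7 without healthy pool 2.

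Markers of B cells and plasma cells had 17 of 22 members higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 1.87 (camera adjusted p = 2.49e-13; adjusted p = 0.0971 with an estimated correlation). CD79A, a part of the B cell receptor, rose by 4.59 ± 0.30 (adjusted p = 0.000155). POU2AF1, a B cell transcriptional coactivator, rose by 4.49 ± 0.39, with healthy pool 3 at 4.76 and the other healthy pools at 4.95 to 4.98, and the kinase PIM2 rose by 4.37 ± 0.47. T cell and NK cell markers had 12 of 25 members higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 7.83e-09; adjusted p = 0.192 with an estimated correlation). The helper T cell receptor CD4 rose by 3.65 ± 0.65 and the costimulatory receptor ICOS by 3.29 ± 0.24. CD4, which dog neutrophils also carry, stood at 10.87 in pyometra pool 1 and at 7.71 to 8.66 in the other pyometra pools. Unlike the neutrophil mean, the means of both lymphocyte lists were lowest in pyometra pool 1, at 1.81 for B cells (2.05 to 2.68 in the other pyometra pools) and, by a margin of 0.04, at 0.89 for T and NK cells (0.93 to 1.69).

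Mast cell markers had 4 of 9 members higher and 1 lower, the same counts as adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0365; adjusted p = 0.155 with an estimated correlation). RAB27B, a regulator of granule release, rose by 2.15 ± 0.31 and the mast cell carboxypeptidase CPA3 by 2.12 ± 0.37. CMA1, the mast cell chymase, rose by 0.80 ± 0.17, and the transcription factor GATA2 changed by -1.14 ± 0.29; both are named after their values were seen. The call of the mast cell list was lost without healthy pool 4 (median 0.20, adjusted p = 0.0666) or pyometra pool 3 (median 0.21, adjusted p = 0.0553), and its median was 0.47 without pyometra pool 1. A filter on dim probe sets left 6 of the 9 members, with a higher median of 1.46, and also ended that call (adjusted p = 0.0533). The call of GATA2 was lost without healthy pool 1 (-1.24), healthy pool 2 (-1.14), pyometra pool 1 (-1.06), pyometra pool 2 (-1.11) or pyometra pool 3 (-1.14).

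Pattern recognition receptors and their signalling proteins had 12 of 32 members higher and 0 lower (18 and 1 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 5.46e-07; adjusted p = 0.278 with an estimated correlation). TLR8, a receptor for single-stranded RNA, rose by 3.78 ± 0.42, with 10.03 in pyometra pool 1 and 8.22 to 8.30 in the other pyometra pools. TLR2, a receptor for bacterial lipoproteins, rose by 3.32 ± 0.47 (adjusted p = 0.0036), with 9.35 in pyometra pool 1 and 7.06 to 7.34 in the others. The inflammatory caspase CASP4, listed with CASP1 as a synonym, rose by 3.60 ± 0.37. TLR4, the lipopolysaccharide receptor, differed by 0.85 ± 0.51 without passing the test (adjusted p = 0.310), with 9.94 in pyometra pool 1 and 7.60 to 7.80 in the others, and by 0.29 without pyometra pool 1. The list's mean over the healthy mean was 1.95 in pyometra pool 1 and 0.86 to 0.92 in the other pyometra pools. Antimicrobial and acute phase proteins had 11 of 25 members higher and 0 lower (14 and 0 adjusted over the list alone), led by SLPI, S100A8 and S100A12, with a median of 1.77 (camera adjusted p = 6.50e-09; adjusted p = 0.127 with an estimated correlation). The neutrophil list shares 9 of its members with other lists, and the antimicrobial list 7.

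Complement proteins, receptors and regulators had 5 of 21 members higher and 0 lower (10 and 1 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.0040; adjusted p = 0.242 with an estimated correlation). C6, a component of the membrane attack complex, rose by 4.33 ± 0.69, and CD55, which protects cells from complement, rose by 3.23 ± 0.63, with 11.81 in pyometra pool 1 and 9.58 to 9.94 in the other pyometra pools. C3, the central complement component, was 3.99-fold higher (SE 0.52 on the log2 scale) and VSIG4, a macrophage receptor of C3 fragments, rose by 1.52 ± 0.33; both are named after their values were seen. The call of C3 was lost without healthy pool 2, healthy pool 3 or pyometra pools 2, 3 or 4 (log2 differences of 1.49 to 2.27 over the 8 fits without a pool), and that of VSIG4 without healthy pool 1 (1.47) or healthy pool 2 (1.41). The complement median was 1.08 over the 17 members left by a filter on dim probe sets. Called complement genes numbered 3 without healthy pool 1 and 2 without healthy pool 2. Antigen presentation genes had 14 of 25 members higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 1.28e-09; adjusted p = 0.192 with an estimated correlation). CD1A6, of the lipid-presenting CD1 family, rose by 3.41 ± 0.46, the lysosomal protease CTSS by 2.40 ± 0.34 and the class II gene DLA-DQA1 by 2.40 ± 0.31, where signal from close relatives in the CD1 and DLA families is not excluded. Genes of leukocyte adhesion and transmigration had 6 of 17 members higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 8.17e-05; adjusted p = 0.113 with an estimated correlation). The hyaluronan receptor CD44 rose by 3.88 ± 0.27 and the integrin ITGAL by 2.67 ± 0.35.

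Genes of prostaglandin and leukotriene synthesis, transport and reception did not move as a list (median 0.26, camera adjusted p = 0.0923; adjusted p = 0.278 with an estimated correlation), although 5 of 28 members were higher and 3 lower (10 and 4 adjusted over the list alone) and fry, which tests a list against no change and not against other genes, gave an adjusted p = 0.0190. PTGS2, the inducible cyclooxygenase, rose by 4.22 ± 0.70 (adjusted p = 0.0067). PLA2G7, which degrades platelet-activating factor, rose by 2.92 ± 0.60, with 11.28 in pyometra pool 1 and 8.71 to 9.11 in the other pyometra pools. Further called members, named after their values were seen, were the prostaglandin receptors PTGDR (1.84 ± 0.36) and PTGIR (0.92 ± 0.16), higher in pyometra, and the synthases PTGIS (-2.29 ± 0.33), PTGDS (-1.30 ± 0.21) and PTGES3 (-0.86 ± 0.22), lower. The call of PTGES3 was lost without healthy pool 1 (-0.76), healthy pool 2 (-0.92), healthy pool 3 (-0.81), pyometra pool 1 (-0.72) or pyometra pool 2 (-0.80). PTGES, the inducible prostaglandin E synthase, differed by 1.86 ± 0.63 without passing the test (adjusted p = 0.0844). The difference of PTGES was 2.37 without pyometra pool 3 (adjusted p = 0.0302) and 1.20 without pyometra pool 1. The mean of this list in healthy pool 4 was -0.28 from the healthy mean, and 0.08 to 0.12 in the other healthy pools.

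Interferon stimulated genes did not move as a list (median -0.55, camera adjusted p = 0.121; adjusted p = 0.836 with an estimated correlation). In limma, 2 of 26 members were higher and 1 lower, 0 and 0 adjusted over the list alone, and 3 and 4 at an unadjusted p under 0.05. They were spread among the healthy pools, where their mean was 0.39, -1.07, 1.37 and -0.69 from the healthy mean in pools 1 to 4. The list was lower without healthy pool 2 (median -1.02, adjusted p = 0.0021) or healthy pool 4 (median -0.85, adjusted p = 0.0275), and its median was -0.14 without healthy pool 3.

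**Figure D3:**
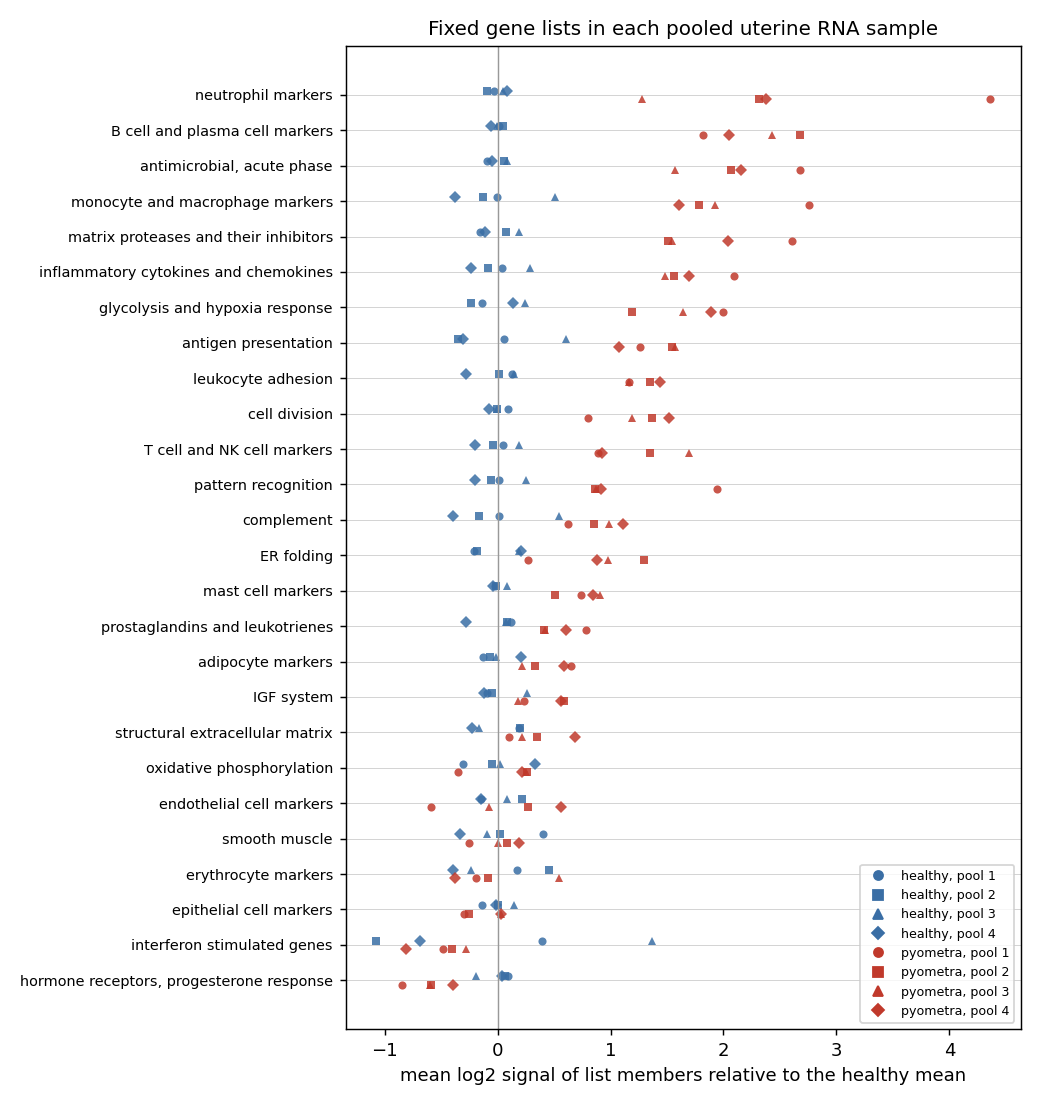
Mean log2 signal of the members of each gene list (horizontal axis, relative to the mean of the 4 healthy pools) for the lists on the vertical axis, where each point is 1 pool (healthy blue, pyometra red) and its shape gives the pool number. The neutrophil markers of pyometra pool 1 lie at 4.36, above the 1.28 to 2.37 of the other pyometra pools, and the interferon stimulated genes of the healthy pools range from -1.07 to 1.37.

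Steroid, growth hormone and prolactin receptors and progesterone response genes fell as a list, with 0 of 29 members higher and 7 lower, the same counts as adjusted over the list alone. Their median difference was -0.40 (camera adjusted p = 0.0039; adjusted p = 0.113 with an estimated correlation) and was -0.61 without healthy pool 1. ESR1, the oestrogen receptor alpha, changed by -2.74 ± 0.55 (adjusted p = 0.0138), with pyometra pool 1 at 6.46 and the other pyometra pools at 8.75 to 9.06. PTCH1, the Hedgehog receptor, changed by -2.28 ± 0.23, with healthy pool 4 at 9.93 and the other healthy pools at 9.30 to 9.40. LIFR, a receptor of leukaemia inhibitory factor, changed by -2.21 ± 0.41, and MSX1, a homeobox transcription factor named after its value was seen, by -1.65 ± 0.28. PGR, the progesterone receptor, differed by -1.74 ± 0.57 without passing the test (adjusted p = 0.0774). Called members of the hormone list numbered 4 without healthy pool 2 or pyometra pool 2. Insulin-like growth factors and their binding proteins did not move as a list (2 of 20 higher and 1 lower, 3 and 1 adjusted over the list alone; median 0.25, camera adjusted p = 0.304). IGFBP5 rose by 2.03 ± 0.25, and the receptor IGF1R changed by -1.57 ± 0.19.

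Markers of the resident tissue did not move as lists. Smooth muscle proteins had 3 of 29 members higher and 2 lower, the same counts as adjusted over the list alone, with a median of -0.05 and a mean of 0.01 (camera adjusted p = 0.812). The intermediate filament DES rose by 2.69 ± 0.34. CSRP1 (0.75 ± 0.17) was higher and SYNPO2 (-1.09 ± 0.31) lower, named after their values were seen, and both depended on single pools. Epithelial markers had 3 of 25 members higher and 4 lower (4 and 4 adjusted over the list alone), with a median of -0.02 (camera adjusted p = 0.812). PROM1 rose by 1.89 ± 0.30, the adhesion protein EPCAM changed by -1.65 ± 0.32 and the epithelial transcription factor GRHL2 by -1.44 ± 0.16. Named after their values were seen, the tight junction protein CLDN7 (0.85 ± 0.18) and the protease ST14 (1.03 ± 0.19) were higher and OCLN (-1.43 ± 0.30) was lower. Endothelial markers had 1 of 23 members higher and 2 lower (5 and 2 adjusted over the list alone), with a median of -0.08, a mean of 0.04 and a test in the upward direction (camera adjusted p = 0.727). Called endothelial members numbered 5 higher and 1 lower without pyometra pool 1, 2 and 1 without healthy pool 4 or pyometra pool 3, 0 and 2 without healthy pool 1, and 0 and 1 without healthy pool 2 or pyometra pools 2 or 4. EMCN, a sialomucin of venous and capillary endothelium, changed by -3.15 ± 0.63 (adjusted p = 0.0138). The medians of these 3 lists changed sign with single pools. The smooth muscle median was 0.02 without healthy pool 1, the endothelial median 0.03 without healthy pool 2 and 0.18 without pyometra pool 1, and the epithelial median 0.16 without healthy pool 3, 0.14 without healthy pool 4 and 0.07 without pyometra pool 2. Scaling turned the epithelial median to 0.05 (quantile normalization), and array weights turned the epithelial and endothelial medians to 0.07 and 0.13. Erythrocyte markers (1 of 8 higher, 0 lower; median -0.03 with a test in the upward direction, camera adjusted p = 0.717) and adipocyte markers (1 of 15 higher, 0 lower; median 0.15, camera adjusted p = 0.184) did not move either, with the same counts adjusted over the list alone. The erythrocyte median was 0.04 without healthy pool 2 and 0.03 without pyometra pool 4, and the adipocyte median 0.05 without healthy pool 2, 0.04 without pyometra pool 1 and 0.07 without pyometra pool 3.

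Structural matrix genes rose as a list, with 5 of 32 members higher and 3 lower (6 and 3 adjusted over the list alone) and a median of 0.45 (camera adjusted p = 0.0365; adjusted p = 0.408 with an estimated correlation). Its call was lost without healthy pool 3 (median 0.46, adjusted p = 0.0712), healthy pool 4 (0.33, adjusted p = 0.0646), pyometra pool 2 (0.41, adjusted p = 0.0531) or pyometra pool 4 (0.36, adjusted p = 0.155), and with quantile normalization (adjusted p = 0.0519). BGN, a small proteoglycan, rose by 2.69 ± 0.22 (adjusted p = 0.000444). The basement membrane collagens COL4A1 (1.62 ± 0.32) and COL4A2 (1.57 ± 0.26) and FBLN2 (1.08 ± 0.22) were higher, and OGN (-2.60 ± 0.38) and TNXB (-1.85 ± 0.31) were lower, all named after their values were seen. Matrix proteases and their inhibitors had 15 of 29 members higher and 0 lower (20 and 1 adjusted over the list alone), with a median of 1.38 (camera adjusted p = 2.45e-08; adjusted p = 0.136 with an estimated correlation). Besides MMP13 and MMP1, the thrombin inhibitor SERPINE2 rose by 4.61 ± 0.51. Called members of this list numbered 9 without healthy pool 1 and 8 without healthy pool 2.

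Cell division genes had 20 of 33 members higher and 0 lower (23 and 2 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 3.30e-11; adjusted p = 0.155 with an estimated correlation). The proliferation marker MKI67 rose by 3.35 ± 0.26 (adjusted p = 0.000335), topoisomerase TOP2A by 2.64 ± 0.36 and the spindle checkpoint kinase BUB1 by 2.32 ± 0.33. Genes of glycolysis and the hypoxia response had 20 of 27 members higher and 0 lower (26 and 0 adjusted over the list alone), with a median of 1.62 (camera adjusted p = 2.75e-14; adjusted p = 0.136 with an estimated correlation). The glucose transporter SLC2A3 rose by 3.79 ± 0.38, the lactate transporter SLC16A3 by 3.25 ± 0.47 and PFKFB3, which makes an activator of glycolysis, by 2.78 ± 0.26. Genes of endoplasmic reticulum folding and the unfolded protein response had 10 of 28 members higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 4.29e-07; adjusted p = 0.278 with an estimated correlation). CRELD2 rose by 1.74 ± 0.24, the disulfide isomerase PDIA4 by 1.68 ± 0.24 and MANF by 1.54 ± 0.29. The mean of this list over the healthy mean was 0.27, 1.29, 0.97 and 0.88 in pyometra pools 1 to 4, where that of the B cell and plasma cell markers was 1.81, 2.68, 2.43 and 2.05. Called members of the endoplasmic reticulum list numbered 20 without pyometra pool 1 and 6 without healthy pool 1, healthy pool 2 or any of the other pyometra pools. Nuclear genes of oxidative phosphorylation did not move as a list (median 0.18, camera adjusted p = 0.539). In limma, 2 of 21 were higher and 0 lower, 0 and 0 adjusted over the list alone, and 3 and 2 at an unadjusted p under 0.05, and their mean over the healthy mean was -0.35 in pyometra pool 1 and 0.22 to 0.26 in the other pyometra pools. Their median was 0.07 without healthy pool 1, 0.34 without healthy pool 4, 0.11 without pyometra pool 2 and 0.09 without pyometra pool 3.

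Further named list members passed the test with all 8 pools, but their calls depended on single pools. The chemokine CCL3 rose by 3.99 ± 0.91, a call lost without healthy pool 1 (4.07), healthy pool 2 (3.90) or pyometra pool 4 (3.70). C5AR1, the C5a receptor, rose by 3.31 ± 0.76, a call lost without healthy pool 1 (3.36) or healthy pool 2 (3.20). The thromboxane synthase TBXAS1 rose by 2.39 ± 0.52 and the lipid synthesis enzyme DGAT2, of the adipocyte list, by 3.47 ± 0.77. Both calls were lost without healthy pool 1 (2.37 and 3.37), healthy pool 2 (2.28 and 3.16) or pyometra pool 4 (2.34 and 3.40). The endothelial MMRN2 rose by 0.76 ± 0.17, lost without healthy pool 1 (0.73), healthy pool 2 (0.77), pyometra pool 2 (0.73) or pyometra pool 4 (0.73), and CSRP1 was lost without healthy pool 1 (0.68), healthy pool 3 (0.68), pyometra pool 2 (0.73) or pyometra pool 4 (0.63). The T cell adhesion protein CD2 rose by 2.32 ± 0.56, lost without healthy pools 1 (2.47), 2 (2.28) or 4 (2.01) or pyometra pools 2 (2.02) or 3 (1.98). The matrix protein TNC rose by 2.68 ± 0.72, lost without healthy pools 3 (2.26) or 4 (2.19) or pyometra pools 1 (2.47), 2 (2.70) or 4 (2.60). PGM5 of the smooth muscle list changed by -1.87 ± 0.49, lost without healthy pools 1 (-1.71), 2 (-1.88) or 3 (-1.73) or pyometra pools 2 (-2.03) or 3 (-1.83). KLF9, named after its value was seen, changed by -0.81 ± 0.18, lost without healthy pool 2 (-0.80), pyometra pool 2 (-0.74) or pyometra pool 4 (-0.76).

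For the rest, most of the 8 fits without a pool lost the call, and values are given with their range over these fits. The integrin ITGAM of neutrophils (3.29 ± 0.82, 2.41 to 3.95) kept its call without pyometra pool 1 or 3, and MS4A2, a chain of the IgE receptor (2.18 ± 0.61, 1.60 to 2.72), and the guanylate-binding protein GBP5 (1.41 ± 0.38, 1.09 to 1.69) kept theirs without pyometra pool 1 or 4. The transcription factor IRF1 (1.58 ± 0.44, 1.22 to 1.87) kept its call without healthy pool 3 or pyometra pool 4, and the antiviral GTPase MX1 (-2.82 ± 0.79, -3.53 to -2.15) kept it without healthy pool 2 alone. SOX17 of the endothelial list (-1.03 ± 0.29, -1.23 to -0.78) kept its call without healthy pool 1 or 3. The collagen COL14A1 (-3.31 ± 0.82, -4.02 to -2.85) and the respiratory chain subunit CYC1 (0.72 ± 0.19, 0.58 to 0.85) kept theirs without healthy pool 4 or pyometra pool 3, and SDHB (0.56 ± 0.16, 0.46 to 0.65) without healthy pool 4 or pyometra pool 1. The integrin ITGA8 (2.04 ± 0.54, 1.58 to 2.58), the RNA-binding protein IGF2BP3 (1.07 ± 0.30, 0.87 to 1.36) and the erythrocyte glycophorin GYPC (1.27 ± 0.35, 1.06 to 1.56) kept their calls without pyometra pool 1 alone. Of genes named after their values were seen, NR2F2 of the hormone list (-1.08 ± 0.30, -1.34 to -0.83) kept its call without pyometra pool 4 alone, and SYNPO2 (-1.24 to -0.83) lost it in every such fit. With all pools, quantile normalization ended the calls of MX1 (-2.81), SOX17 (-0.99) and IGF2BP3 (1.06), median centring those of IGF2BP3 (1.06), GYPC (1.25) and SDHB (0.54), moderation with trend and robust settings those of SOX17, CYC1 and SDHB, and array weights those of MX1 (-2.69) and IRF1 (1.35). The block for the replicate number ended 14 calls of genes named by the rule. They were MS4A2, TBXAS1, GBP5, ITGAM, SOX17, MMRN2, ITGA8, PGM5, IGF2BP3, COL14A1, DGAT2, CYC1, SDHB and LIFR (limma adjusted p = 0.0545).

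Small counts of called list members moved with single pools as well. Smooth muscle genes had 1 higher and 0 lower without healthy pools 1 or 3 or pyometra pool 2, 2 and 0 without healthy pool 2 or pyometra pool 3, 1 and 1 without pyometra pool 4, and 3 and 1 without pyometra pool 1. Genes of the insulin-like growth factor list had 1 higher and 1 lower without healthy pools 1 or 2 or pyometra pools 2 or 4, 1 and 2 without healthy pool 4, and 4 and 1 without pyometra pool 1. Interferon stimulated genes had 0 higher and 0 lower without healthy pool 1 or pyometra pools 2 or 3, 0 and 1 without healthy pools 2 or 4, 2 and 0 without healthy pool 3, 1 and 0 without pyometra pool 1, and 3 and 0 without pyometra pool 4. Mast cell markers had 3 higher and 0 lower without healthy pools 1 or 2 or pyometra pools 2 or 3, and 4 and 0 without pyometra pool 1. Epithelial markers had 5 higher and 4 lower without healthy pool 3. Oxidative phosphorylation genes had 0 higher without healthy pools 1, 2 or 3 or pyometra pools 2 or 4, and 1 without pyometra pool 3. Erythrocyte markers had 0 called members without any of the healthy pools or without pyometra pools 2 or 3, and adipocyte markers 0 without healthy pools 1 or 2 or pyometra pool 4. A lower member appeared among pattern recognition genes without pyometra pool 1 (14 higher, 1 lower), among complement genes without healthy pool 4 (5 and 1) and among matrix proteases without pyometra pool 4 (12 and 1).

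The 4 pyometra values lay beyond all 4 healthy values in the direction of the difference for every gene of the 26 lists, or among the largest changes, that is said to have risen, fallen or changed, except IRF1, IGF2BP3 and COL14A1. For the largest changes the naming rule required this, so that it is no result about them. Most of the other genes were picked for being called, which favours such separation, so that it adds little for them either. Of the 26 lists, 16 rose and 1 fell with camera at the preset correlation. With an estimated correlation, 0 lists passed after adjustment (lowest adjusted p = 0.0971) and 7 had an unadjusted p under 0.05. In fry, the test against no change, 17 lists passed.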

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

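The tests of leukocyte numbers and of the neutrophil share in pyometra pool 1, with the comparison of each leukocyte list with random lists, of dilution, of loss of epithelium, and of macrophage and other leukocyte shares behind the spread of interferon genes, and the grouping of the splits by kind, were chosen only after the result was seen.

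The main counts were taken in all 35 splits of the 8 pools into groups of 4. For the number of genes called (3116) and of genes called at least 2-fold (1838), 1 of the 35 splits, the real one, gave as many. The highest of the other splits gave 0 in both cases. Every other split mixed healthy and pyometra pools, which puts the difference between the groups into the spread within them. Low counts are then likely, so that these splits cannot exclude chance. For the number of gene lists called (17), 5 splits gave as many, with up to 19 in another split, so that chance was not excluded. The 4 other splits with as many each set 3 pools of a group with 1 of the other and so kept part of the real contrast, and the 18 splits with 2 pools of each group on both sides called 2 to 10 lists.

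Of 234 groups of 4 pools examined, 16 (6.84%) held a pool far from the other pools of its group, where chance gives about 5%, or 11.7 groups, so that single values may be chance; 9 of these were pyometra pool 1, 4 healthy pool 3 and 3 healthy pool 4. Each value is the gap between that pool and its nearest neighbour as a share of the group's range. In pyometra pool 1 the gap was 0.940 for TYROBP (11.10 against 9.34 to 9.45), 0.955 for TLR8 (10.03 against 8.22 to 8.30), 0.877 for TLR2 (9.35 against 7.06 to 7.34) and 0.913 for TLR4 (9.94 against 7.60 to 7.80). It was 0.843 for PLA2G7 (11.28 against 8.71 to 9.11), 0.835 for CD55 (11.81 against 9.58 to 9.94) and 0.948 for the pattern recognition list (1.95 against 0.86 to 0.92), all with pyometra pool 1 the highest. The same pool was the lowest for ESR1 (0.882; 6.46 against 8.75 to 9.06) and for the oxidative phosphorylation list (0.932; -0.35 against 0.22 to 0.26). Healthy pool 3 was the highest for MMP13 (0.868; 4.26 against 3.99 to 4.02), ATP12A (0.879; 6.67 against 3.87 to 4.21) and TNF (0.909; 4.65 against 4.25 to 4.28), and the lowest for POU2AF1 (0.879; 4.76 against 4.95 to 4.98). Healthy pool 4 was the highest for MIR218-1 (0.928; 9.55 against 6.39 to 6.62) and PTCH1 (0.842; 9.93 against 9.30 to 9.40), and the lowest for the prostaglandin and leukotriene list (0.892; -0.28 against 0.08 to 0.12).

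Pyometra pool 1 stood apart from the other pyometra pools in 9 of these groups, and its array had the narrowest signals (SD 1.98, against 2.02 to 2.04). A narrower signal range was argued against, since neutrophil markers still deviated by 2.51 in that pool after the trend on signal level was removed, outside the -0.20 to 0.40 of random lists, and the trend held 7.33% of the variance. List means cannot decide on more leukocytes of every kind, since at 100 ng of RNA per pool they follow shares of RNA and not cell numbers. In shares, 2 of the 4 leukocyte lists lay below every other pyometra pool. The B cell list deviated by -0.57 (random lists -0.49 to 0.19) and the T and NK cell list by -0.43 (random lists -0.27 to 0.29). The latter lay only 0.04 below the next pool, and CD4 (10.87) and the leukocyte antigen PTPRC (10.38) were highest in pyometra pool 1. Random lists were drawn gene by gene, whereas the estimated correlation was 0.169 (B cell), 0.385 (T and NK cell), 0.484 (macrophage) and 0.565 (neutrophil). Such ranges are too narrow for correlated genes, so that the lymphocyte deviations are not shown to exceed chance. A larger share of neutrophil RNA in that pool may account for the pattern: the 23 neutrophil markers, of which 3 lie above the median gene in healthy uterus and 9 stand in other lists, deviated by 2.37 (random lists -0.34 to 0.26), and S100A9, S100A12 and S100A8 reached 12.41, 12.07 and 11.47. The comparison of neutrophil markers with random lists was chosen after the result was seen, so that it restates their height in that pool and does not test the cause. Macrophage markers also deviated (0.99, random lists -0.53 to 0.24), so that a larger macrophage share stays open, as does what set these dogs apart, since the labels say nothing of the dogs in a pool.

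The 1584 genes lower in pyometra had a median difference of -1.02. Even dilution of all resident uterine RNA by leukocyte RNA was set against the smooth muscle list. It lay 0.973 above that median, more than the SD of its members (0.874). The test cannot decide on dilution, since that median comes from genes picked for being lower and a list that did not move lies above it anyway. The values show only that smooth muscle markers (median -0.05) did not fall as far as the lower genes, and a shallower dilution stays open. Loss of epithelium alone cannot be told apart from other causes, since the epithelial list lay 1.003 above that median with an SD of its members of 1.07, and its members went both ways. Lower expression within resident cells, and loss of a cell type without a list here, stay open and were not tested. The disease itself, which the design names, stays among the open explanations.

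Interferon stimulated genes were spread over the healthy pools by 2.44 on the log2 scale, with a mean of 1.37 in healthy pool 3 and -1.07 in healthy pool 2. An order of the pools set by a few members was argued against, since 25 of 26 members (96.2%) had their highest healthy value in pool 3 and 21 their lowest in pool 2. The count ignores sizes, so that it does not show whether some members make up most of the 2.44. In healthy pools 3 and 2, MX1 stood at 11.09 and 6.93 and IRF1 at 7.31 and 6.34. A different share of macrophages as the whole cause was argued against: macrophage markers were also highest in healthy pool 3, but their mean was 0.635 above that in healthy pool 2 (SD of the members 0.551), against 2.44 for the interferon genes, and 11 of the 16 lay at least 1 above the arrays' lower quartile, taken as background. Of 70 neutrophil, B cell, T cell and NK cell markers, 28 lay that far above background. The test took these lists together and could not tell, since most markers did not lie that far above background. Reading the B cell list alone was not part of that test, so that no verdict is drawn from it. In it, 11 of 22 markers lay that far above background. The B cell mean in healthy pool 3 was -0.05 relative to healthy pool 2 (SD of the members 0.40), against 2.44 for the interferon genes. Different shares of neutrophils or of T and NK cells cannot be told apart, since 7 of 23 and 10 of 25 markers lay that far above background. Their means differed by 0.147 (SD 0.907) and 0.231 (SD 0.321) between the same pools. A difference between the dogs of these pools stays open and was not tested, since the labels give no groups within the healthy dogs.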

How the results depend on the processing

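The test of 1-symbol probe sets alone and the counts of list members without each pool or after the dim filter were chosen only after the result was seen. Of 91 named genes, 67 kept their direction and their side of the threshold in every alternative that was run for single genes. In those of them that kept all pools, 73 did so, and 0 were reversed in any. The adjusted p under 0.01 was not among these alternatives, and called genes such as IL1B (limma adjusted p = 0.0176) do not pass it. Between 1458 and 1938 genes were higher and between 1408 and 1932 lower under quantile normalization, median centring, the filter on dim probe sets, the mean of probe sets, moderation with trend and robust settings, array weights and the 1-symbol test. Without a pool, genes higher ranged from 933 to 1706 and genes lower from 823 to 1467. Fewer pools leave fewer degrees of freedom, but without pyometra pool 1 the higher count was above that with all pools. An adjusted p under 0.01 left 623 genes higher and 452 lower, and 547 and 356 at least 2-fold, by its construction. A block for the replicate number left 851 genes lower (1067 higher) and kept 1804 of the 3116 calls. The labels do not say whether pools with the same number are paired or share a batch. Deviations of pools with the same number correlated at -0.127, 0.0280, 0.000160 and -0.0120. These values do not settle it, since pools with different numbers were not compared in this way.

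Gene lists lower numbered 2 with the replicate block, where interferon stimulated genes (median -0.55, adjusted p = 0.0414) joined the hormone list, and 1 to 2 without a pool, and the cause was not tested. With an estimated correlation, 0 lists were higher and 0 lower. The estimated correlation lay above the preset 0.01 in every called list except the mast cell and hormone lists, and reached 0.565 for neutrophil, 0.504 for endoplasmic reticulum and 0.484 for macrophage genes. The preset p-values of such lists therefore rest on a correlation lower than the data gave. The mast cell (-0.020) and hormone (-0.003) lists lost their calls too, so that this is not the whole cause, and the rest was not tested. The list medians that changed sign lay near 0. They were the epithelial list at 0.0499 with quantile normalization and 0.0710 with array weights, and the endothelial list at 0.130 with array weights, and the cause was not tested. Without a pool, medians ranged from -0.0710 to 0.0205 for smooth muscle, -0.180 to 0.183 for endothelial, -0.214 to 0.163 for epithelial and -0.0652 to 0.0425 for erythrocyte markers. The structural matrix list was not past the threshold with quantile normalization (adjusted p = 0.0519), nor the mast cell list with the dim filter (0.0533, with a median of 1.46 over the 6 members left), and in fry, which tests against no change, the structural matrix list had an adjusted p = 0.0509 and the prostaglandin and leukotriene list 0.0190. TNF passed with array weights (1.67, adjusted p = 0.0317). Low signal limits what can be seen, since the values carry no detection calls and levels near 4 lie close to the lower quartile of the arrays (3.97 to 4.13).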

Other observations

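The lists of Hedgehog, FGF and Slit, Wnt, nerve, kynurenine and epithelial transport genes, all genes named beside them and the count of genes that divide the healthy pools were chosen only after the result was seen. Since these lists were made with the values of some members known, counts and medians are given for them and no list test.

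In a list of Hedgehog, FGF and Slit signalling, 8 of 26 members were lower in pyometra, 1 was higher and 17 did not pass the test, with a median difference of -0.55. FGF9, a growth factor, changed by -3.11 ± 0.57, FGF12 by -2.87 ± 0.58, the receptor FGFR1 by -1.95 ± 0.34 and the Hedgehog transcription factor GLI2 by -1.38 ± 0.25, besides SLIT2 and PTCH1. SMO, the Hedgehog signal transducer, changed by -1.23 ± 0.28, and its call was lost without healthy pool 1 (-1.12) or pyometra pool 2 (-1.20). The call of the receptor ROBO1 (-1.81 ± 0.47, -2.18 to -1.51 over the fits without a pool) was kept only without healthy pool 3 or pyometra pool 3, and that of FGFR3, the higher member (0.62 ± 0.17, 0.53 to 0.74), only without healthy pool 3 or pyometra pool 2. Wnt genes went both ways (6 of 42 higher and 7 lower, median -0.01), with NDP (-3.05 ± 0.30), the receptor FZD3 (-2.77 ± 0.25), LGR4 (-2.07 ± 0.40) and the transcription factor LEF1 (-2.02 ± 0.38) among the lower members. Of the higher members, DKK2, a Wnt antagonist (2.06 ± 0.38), and WNT16 (0.89 ± 0.15) kept their calls without any single pool. DKK3 (1.89 ± 0.53, 1.36 to 2.26 over the fits without a pool) kept its call only without healthy pools 2 or 4, WNT5A (1.28 ± 0.34, 0.98 to 1.44) only without healthy pool 4, and WNT7B (0.44 ± 0.11, 0.38 to 0.49) and LGR6 (0.54 ± 0.15, 0.40 to 0.60) only without pyometra pool 1. Of 19 nerve genes, 0 were higher and 2 lower in limma (median 0.07). The lower members, NCAM1 (-0.57 ± 0.15, -0.69 to -0.49) and PMP22 (-1.29 ± 0.31, -1.59 to -1.12), kept their calls only without healthy pool 4 or pyometra pool 1.

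Of 11 genes of tryptophan breakdown through kynurenine, 4 were higher and 0 lower (median 0.81). KMO, the kynurenine monooxygenase, rose by 4.28 ± 0.46 (adjusted p = 0.0012). IDO1, which opens the pathway, rose by 3.20 ± 0.88, a call kept without healthy pool 3 or pyometra pool 1 but lost in the other 6 fits without a pool (lowest value 2.76). The groups overlapped in IDO1, ROBO1 and FGFR3. KYNU (1.69 ± 0.46, 1.21 to 2.03) kept its call only without pyometra pool 1 or 4, and HAAO (1.49 ± 0.37, 1.14 to 1.79) only without pyometra pools 1, 3 or 4. Of 23 epithelial transport genes, 6 were higher and 1 lower (median 0.23). Among them, the amino acid transporter SLC6A14 rose by 4.04 ± 0.48, the anion exchanger SLC26A4 by 4.02 ± 0.55, the cystine transporter SLC7A11 by 3.78 ± 0.78 and the potassium channel KCNN4 by 1.90 ± 0.30, while the chloride channel ANO1 changed by -1.83 ± 0.30. The chloride channel CFTR rose by 3.04 ± 0.68, a call lost without pyometra pool 4 (2.85). PTPRC, the CD45 antigen of all leukocytes, rose by 3.29 ± 0.41.

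Healthy pools 1 and 2 differed from healthy pools 3 and 4 in 9 genes by at least 3 on the log2 scale, with at most 1 between the pools of a pair, and 0 genes did so for any other pairing; no test was run. ADAMTS19 (10.34 and 11.12 against 5.67 and 5.21), CLDN10 (10.62 and 10.92 against 4.22 and 4.39), CAPN6 and PTPRR were high in pools 1 and 2. DEFB1, a beta-defensin (10.62 and 11.29 against 5.31 and 5.18), NEBL, ATP6V1C2, PRXL2A and SLC7A2 were high in pools 3 and 4.

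Probe sets without a single gene symbol numbered 15513, of which 558 were higher and 1096 lower in pyometra. The largest differences among those without any symbol were 7.52 ± 0.36 (probe set 14305099) and 6.98 ± 0.85 (14443153) upward, and -3.65 ± 0.52 (14384371) and -3.11 ± 0.30 (14458769) downward. Their genes are not named in the annotation used here.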
